A study of Arabidopsis thaliana with 20 samples.

How the data were processed

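RNA from sections of the primary inflorescence stem of Arabidopsis thaliana, accession Ler, was compared on 20 spotted arrays, each hybridised with a pair of dye-labelled cDNAs. Per the labels, plants were grown in 8 h short days and then moved to 16 h long days. Stems about 5 cm long were harvested on day 12 after the change and stems about 10 cm long on day 14. Flowers, siliques, leaves and side branches were removed. Sections are named by their distance from the tip. The 10 cm stems gave sections of 0-3, 3-5, 5-7 and 7-9 cm, and the 5 cm stems gave sections of 0-2 and 2-4 cm. Every array set a section against the 0-2 cm section of the 5 cm stems, which served as the common reference. There were 4 arrays for each of the other 5 sections. In each group the section carried Cy5 on 2 arrays and Cy3 on the other 2. The labels do not say whether the 4 replicates came from separate plants, so p-values measure the spread between these arrays, which may be technical.

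The deposited values are log ratios on a scale centred near 0. Their log base is not stated in the labels and was taken as 2, so the folds depend on that choice, whereas the tests do not. The authors scanned the arrays with a ScanArray Express scanner, per the labels. Background correction, normalization and software are not given in the sources used here, so the authors' centring and scaling stay unknown. Spot intensities were not used here, so distance from background is unknown and precision is limited by the number of arrays. The log2 direction was taken as section over 0-2 cm reference, as the deposited titles order them. Arrays of opposite dye correlated above 0 within their groups, apart from 0-3 cm replicates 1 and 3 (r = -0.211 over probes), so the deposited values had already been turned to 1 direction. Array medians were -0.025, -0.018, 0 and -0.021 for 0-3 cm replicates 1 to 4. They were 0.002, 0.026, -0.01 and -0.018 for 2-4 cm, and -0.008, 0, -0.008 and -0.001 for 3-5 cm. For 5-7 cm they were 0.038, 0, 0.019 and -0.024, and for 7-9 cm 0.029, -0.022, 0 and -0.033. The values of 0-3 cm replicate 3, 5-7 cm replicate 2 and 7-9 cm replicate 3 were deposited in steps of 0.1. No pair of arrays held identical values, and the highest correlation between arrays of a group was 0.869.

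Labels were inconsistent in several places. For 3-5 cm replicate 1 the source name gives a 5 cm stem, and the title was followed. For 5-7 cm replicate 4 and 7-9 cm replicates 2 and 4 the source name and the description give different dyes. The source name was used: the correlation of these arrays with the dye effect of the others was 0.394, 0.253 and 0.305, positive as on the Cy5 array 5-7 cm replicate 2 (0.312) and unlike the Cy3 arrays (-0.328 to -0.271). Array 0-3 cm replicate 2 was scanned at 95% laser power and the others at 90%. Photomultiplier settings formed a technical batch. All 0-3 cm arrays and replicates 1 and 2 of 5-7 and 7-9 cm were scanned at 62 and 60, and replicates 3 and 4 of 5-7 and 7-9 cm at 63 and 60. The 2-4 cm arrays alone had 62 and 59, and the 3-5 cm arrays alone 62 and 61, so setting and group cannot be told apart for these sections. Array numbers ran by section: 2 to 5 for 2-4 cm, 6 to 9 for 0-3 cm and 10 to 13 for 3-5 cm. The 5-7 and 7-9 cm arrays alternated in pairs from 14 to 21. Except between these last sections, array number and section cannot be told apart.

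The array had 28800 spots in 48 blocks of 600. Of these, 3061 were blank on every array and 25739 had a value, 25270 of them on all 20 arrays. Probes were tested if measured on at least 3 of the 4 arrays of every group, which kept 25720. The platform annotation used here listed 8519 probes, 8338 with 1 gene and 181 with several, and 8302 of the former matched a gene of the TAIR10.1 RefSeq table, which was used for names only. Probes with several genes were not named, and 17376 measured spots were unnamed here. The tested probes included 8138 with 1 gene, from 7871 loci, and 413 matched probes belonged to loci annotated as pseudogenes. The pairing of annotation and spot numbers was checked: 156 annotated probes fell on blank spots, against 777 to 952 when the numbers were shifted by 1 to 3 spots. For loci with several probes, the probe measured on most arrays stood for the locus in gene lists. The median correlation of such probes was 0.0531 over 505 pairs, of which 231 came from 1 locus, and 0.0908 with 1 pair for each of 229 loci (random pairs, -0.0175). For the 3 pairs in which both probes had an SD over 1 it was 0.879. With 1 pair per locus, 43 of 55 loci with both probes changed in the 7-9 cm section went the same way. A gene's value is that of its probe.

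Tests used limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 5 groups and a dye term was fitted to the log2 ratios of all 20 arrays (14 residual degrees of freedom), followed by eBayes. Each section was tested against the reference as the group mean against 0. The reference is the control's RNA and had no arrays of its own, so this test leaves out the control's own spread. Pairs of sections were tested as differences of group means, the trend along the 10 cm stems as a linear contrast over section midpoints of 1.5, 4, 6 and 8 cm, and all differences among these 4 sections with a moderated F test. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probes of a comparison, with a threshold of 0.05. Standard errors (SE) are those of the moderated model. Comparisons with the same reference share its chance values, so no overlap of calls between them is used as evidence here.

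Gene lists were tested with cameraPR on the moderated statistics, with a preset correlation of 0.01, for lists with at least 5 measured members, and adjusted over the lists of a comparison. The correlation was also estimated from the data. Of 31 list calls, 19 held with the estimated correlation. Adjusted p-values printed first use the preset correlation and can lie far below the highest under the alternatives. That highest value is given beside them for ribosomal protein genes. Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined, with the exceptions named here. Of 25 lists fixed then, with 410 genes, only 35 genes were measured and named. Only 2 lists could be tested (expansins and xyloglucan endotransglucosylases, and photosynthesis). Members count as measured only where a probe named here measured them. Others may lie among the unnamed spots, so a list with 0 measured members says nothing about its genes. The lists for monolignol biosynthesis, the methionine and methyl group cycle, secondary wall NAC and MYB regulators, xylem cell death, phloem markers, cuticle and epidermis, defence and senescence, floral organ identity, tapetum and pollen wall, shoot meristem and reference genes had 0 measured members and gave no result. The other 12 fixed lists had 1 to 4 measured members and were not tested as lists. A further 19 lists were chosen after the probe annotation was seen and before any gene or list value was seen, and 17 of them could be tested (added lists; laccases and fasciclin-like proteins had 0 measured members). The added lists were cytosolic ribosomal proteins, photosynthesis with chlorophyll synthesis, class III peroxidases, pectin methylesterases, histones, spindle with replication and cell division, trichome birefringence-like acetyltransferases, all named expansins and xyloglucan endotransglucosylases, family 9 glycosyl hydrolases, auxin response, glucosyltransferases, serine carboxypeptidase-like genes, cold with drought and late embryogenesis genes, glutathione S-transferases and, as markers of other tissue, pollen with tapetum and egg cell, and lateral organ primordia; 1 further list is not reported here.

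Genes were named by rule: per comparison, the 5 highest and 5 lowest log2 values among changed probes with 1 gene, measured on every array of the section and with the same direction on each (for pairs of sections, without overlap between the groups), and up to 4 changed members of each list. The steps were tested on simulated data with the real spread. For the 7-9 cm section against the reference, 8%, 82%, 100% and 100% of 50 probes changed by 0.5, 1, 1.5 and 2 on the log2 scale were recovered among 25720 probes, with 3.33% false calls. For 7-9 against 5-7 cm, 4%, 40%, 82% and 100% were recovered, with 4.24% false calls. For the trend, 2%, 54%, 88% and 98% were recovered over the distance of 6.5 cm, with 3.2% false calls. For the F test, 98% of 200 probes changed by 2 were recovered, with 2.97% false calls. The noise was drawn independently for each probe and array, without spot trends or links between arrays. False calls under such trends or links were therefore not tested. Few probes were changed, so recovery may differ in real comparisons where many change.

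Alternatives covered the replicate number as a block, the dye term, centring and scaling of arrays, the probe filter, the arrays in the model, random blocks of array pairs, robust eBayes, array weights, a minimum log2 of 1, the dyes of the descriptions, each array left out in turn, the mean over a locus's probes and the estimated correlation. Added after the data were seen were the removal of a running median over neighbouring spots, a block for the scanner setting, models within a scanner setting, the replicate number as a block on the 5-7 and 7-9 cm arrays alone, and a model without the 3 arrays whose labels name different dyes.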

Results

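The series profiled transcripts along the growing primary inflorescence stem of Arabidopsis, from the tip, where tissue is youngest, towards older tissue further down. Log2 ratios of 5 stem sections over the 0-2 cm section of 5 cm stems were available for 25720 tested probes, on 4 arrays per section. The sections were 0-3, 3-5, 5-7 and 7-9 cm of 10 cm stems and 2-4 cm of 5 cm stems. Correlations between arrays of a group, across probes, ran from -0.211 to 0.551 for 0-3 cm, 0.131 to 0.578 for 2-4 cm, 0.743 to 0.869 for 3-5 cm, 0.572 to 0.799 for 5-7 cm and 0.649 to 0.819 for 7-9 cm. The SD of the ratios on an array lay between 0.412 and 0.925. Values below are log2 ratios with their SE, each from n = 4 arrays per section, and adjusted p-values are from limma.

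**Figure D1:**
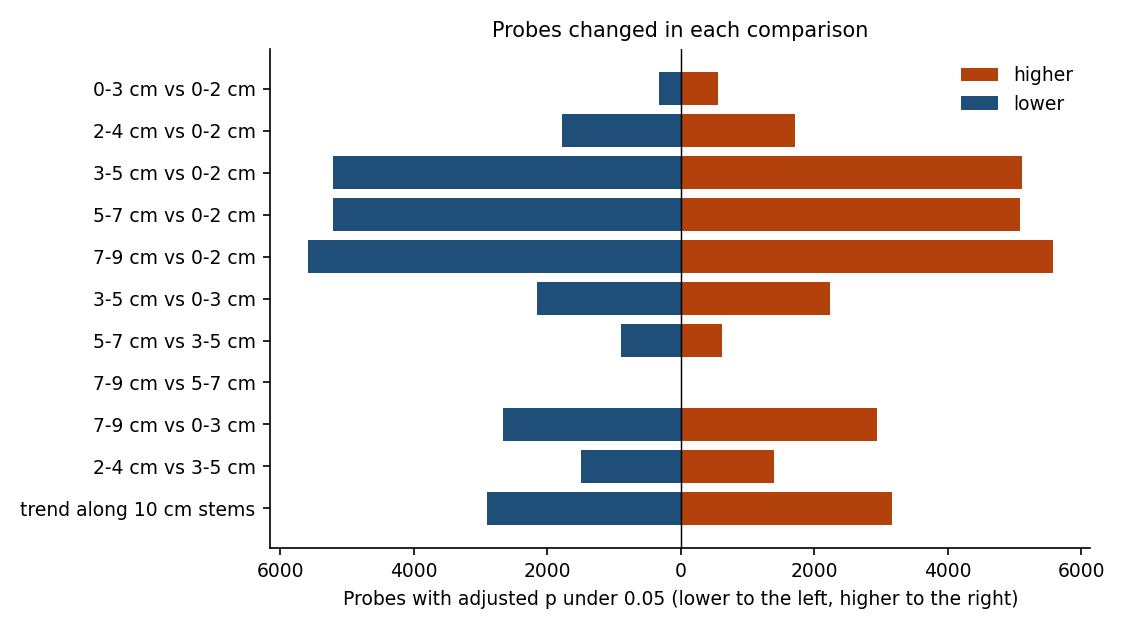
Number of probes with an adjusted p under 0.05 in each comparison (x axis, probes; lower to the left, higher to the right), for 11 comparisons. The 7-9 cm section had the most changed probes against the 0-2 cm reference (11163), and 7-9 against 5-7 cm had 1.

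The first comparison asked how the uppermost 3 cm of 10 cm stems differed from the uppermost 2 cm of 5 cm stems. Several expansin and related wall genes were higher in the 0-3 cm section. EXPA8 (AT2G40610), an expansin, was higher by 1.63 ± 0.227 (adjusted p = 0.000151). XTH33 (AT1G10550), a xyloglucan endotransglucosylase, was higher by 1.64 ± 0.172 (adjusted p = 7.31e-06), and the expansin-like genes EXLA1 and EXLA2 by 1.71 ± 0.124 and 1.21 ± 0.211. BGLU46 (AT1G61820), a beta-glucosidase that acts on monolignol glucosides, rose by 2.59 ± 0.336, and AT3G03960, a subunit of the cytosolic TCP-1 chaperonin, by 2.99 ± 0.154. The amine oxidase family genes AT1G31690 (-1.39 ± 0.254) and AT1G31710 (-1.17 ± 0.205) were lower.

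Of 5 measured expansins and xyloglucan endotransglucosylases in the fixed list, 2 rose and 3 did not pass in the 0-3 cm section (median 0.21, mean 0.68, adjusted p = 2.99e-05), and adjusted over the list alone the count was also 2. The added list of all 16 named members had 4 higher and 0 lower (median 0.045, adjusted p = 8.18e-06, and adjusted p = 0.0592 with an estimated correlation). Its median was 0.017 without 0-3 cm replicate 1 and 0.099 without replicate 2 or without replicate 4, and that of the fixed list was 0.41 without replicate 3. With array weights and with local spot trends removed the median of all 16 was 0.019 and 0.088. Among 89 cytosolic ribosomal protein genes of an added list, 14 fell, 0 rose and 75 did not pass (median -0.47, adjusted p = 9.06e-13, at most 0.0406 under the alternatives). In all, 892 probes changed, 561 higher and 331 lower. The count was 336 without 0-3 cm replicate 2 and 370 without replicate 4. With the scanner setting as a block it was 1069, and among arrays scanned at 62 and 60 it was 498. It rose to 2821 with centring and scaling, 2299 with array weights, 1986 with only the compared arrays and 1974 with random blocks of replicates 1 with 3 and 2 with 4, and was 466 with random blocks of 1 with 2 and 3 with 4.

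The 2-4 cm section of 5 cm stems was set against the section just above it on the same stems. Among wall genes, XTH33 was higher by 2.32 ± 0.172 (adjusted p = 2.18e-08), EXPA8 by 1.90 ± 0.227 and EXPA15 (AT2G03090) by 1.25 ± 0.169. TBL33 (AT2G40320) and TBL37 (AT2G34070), of the family that acetylates wall polysaccharides, rose by 2.32 ± 0.256 and 1.31 ± 0.149, and ATPMEPCRD (AT2G43050), a pectin methylesterase, by 1.72 ± 0.222. LTI30 (AT3G50970), a dehydrin, rose by 1.34 ± 0.133. ARPN (AT2G02850), a plantacyanin, fell by 2.16 ± 0.292, the drought-induced gene DI21 (AT4G15910) by 1.67 ± 0.187, the Aurora kinase gene AUR2 (AT2G25880) by 0.95 ± 0.184 and the histone H2B gene HTB2 (AT5G22880) by 0.86 ± 0.171.

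In the fixed list of expansins and xyloglucan endotransglucosylases, 3 of 5 rose (median 1.25, adjusted p = 8.48e-09), and adjusted over the list alone 4 rose. Of all 16 named members, 4 rose (median 0.30, adjusted p = 1.56e-05). Ribosomal protein genes were lower, with 37 of 89 down, 1 up and 51 not passing (median -0.53, adjusted p = 1.77e-13, at most 0.0376 under the alternatives). AT1G41880 and AT5G22440, both ribosomal protein genes, fell by 1.37 ± 0.175 and 1.32 ± 0.172. Among 16 trichome birefringence-like genes, 5 rose and 1 fell (median 0.005, mean 0.32, adjusted p = 0.0307, and adjusted p = 0.194 with an estimated correlation). This list call ended without 2-4 cm replicate 3 (adjusted p = 0.0684, median 0.15) and without replicate 4 (adjusted p = 0.0708, median -0.015), and its median was 0.018 without replicate 1 and 0.013 without replicate 2. The median turned to -0.009 with centring and scaling, -0.021 with array weights and -0.029 with local spot trends removed (adjusted p = 0.0161, 0.0175 and 0.0172). In total 3478 probes changed, 1706 higher and 1772 lower, and the count was 1994 without 2-4 cm replicate 1, 2142 without replicate 3 and 2067 without replicate 4. Centring and scaling gave 6200, array weights 5327 and random blocks of replicates 1 with 2 and 3 with 4 gave 2169.

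The 3-5 cm section of 10 cm stems differed far more widely from the reference. Expression of AT2G37130 and AT4G37520, both class III peroxidase genes, was higher by 5.77 ± 0.379 (adjusted p = 2.02e-10) and 3.70 ± 0.248. GSTF3 (AT2G02930), a glutathione S-transferase, rose by 4.71 ± 0.219 and BGLU46 by 4.57 ± 0.336. ATPMEPCRD rose by 3.73 ± 0.222 and TBL33 by 3.45 ± 0.256. AT1G22410 (DHS3), which encodes a first enzyme of the shikimate pathway, rose by 2.06 ± 0.297 (adjusted p = 8.77e-06). PRXCA (AT3G49110), another class III peroxidase, fell by 3.72 ± 0.34, the plastid chaperonin gene Cpn60beta2 (AT3G13470) by 3.55 ± 0.297 and ARPN by 3.44 ± 0.292.

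Ribosomal protein genes fell as a group in the 3-5 cm section, with 79 of 89 down, 2 up and 8 not passing (median -1.80, adjusted p = 1.88e-38, at most 0.00198 under the alternatives). Among them were AT2G01250 (-2.64 ± 0.217) and AT5G22440 (-2.57 ± 0.172). Of 22 genes of spindle, replication and cell division, 13 fell and 2 rose (median -0.69, adjusted p = 0.0128, and adjusted p = 0.196 with an estimated correlation). In this list TOPII (AT3G23890), topoisomerase II, fell by 2.08 ± 0.301, AUR2 by 1.86 ± 0.184 and PRL (AT4G02060), the replication licensing factor MCM7, by 1.60 ± 0.288, whereas ATMAP65-6 (AT2G01910), which binds microtubules, rose by 2.11 ± 0.158. Of the 5 expansins and xyloglucan endotransglucosylases in the fixed list 3 rose, EXPA8 by 2.09 ± 0.227, XTH33 by 2.07 ± 0.172 and EXGT-A3 (AT2G01850) by 1.295 ± 0.171. Adjusted over the list alone the count was also 3 (median 1.295, adjusted p = 0.0128, and adjusted p = 0.155 with an estimated correlation). PHV (AT1G30490), a homeodomain regulator of vascular and organ patterning, was lower (-1.06 ± 0.201), and the tetrapyrrole synthesis genes HEME1 (AT3G14930) and HEME2 (AT2G40490) fell by 1.64 ± 0.206 and 1.83 ± 0.342. The fixed photosynthesis list was not called (median 0.52, adjusted p = 0.525), with 2 of 8 members higher, as when adjusted over the list alone. Altogether 10323 probes changed, 5116 higher and 5207 lower, and 3466 changed at least 2-fold.

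**Figure D2:**
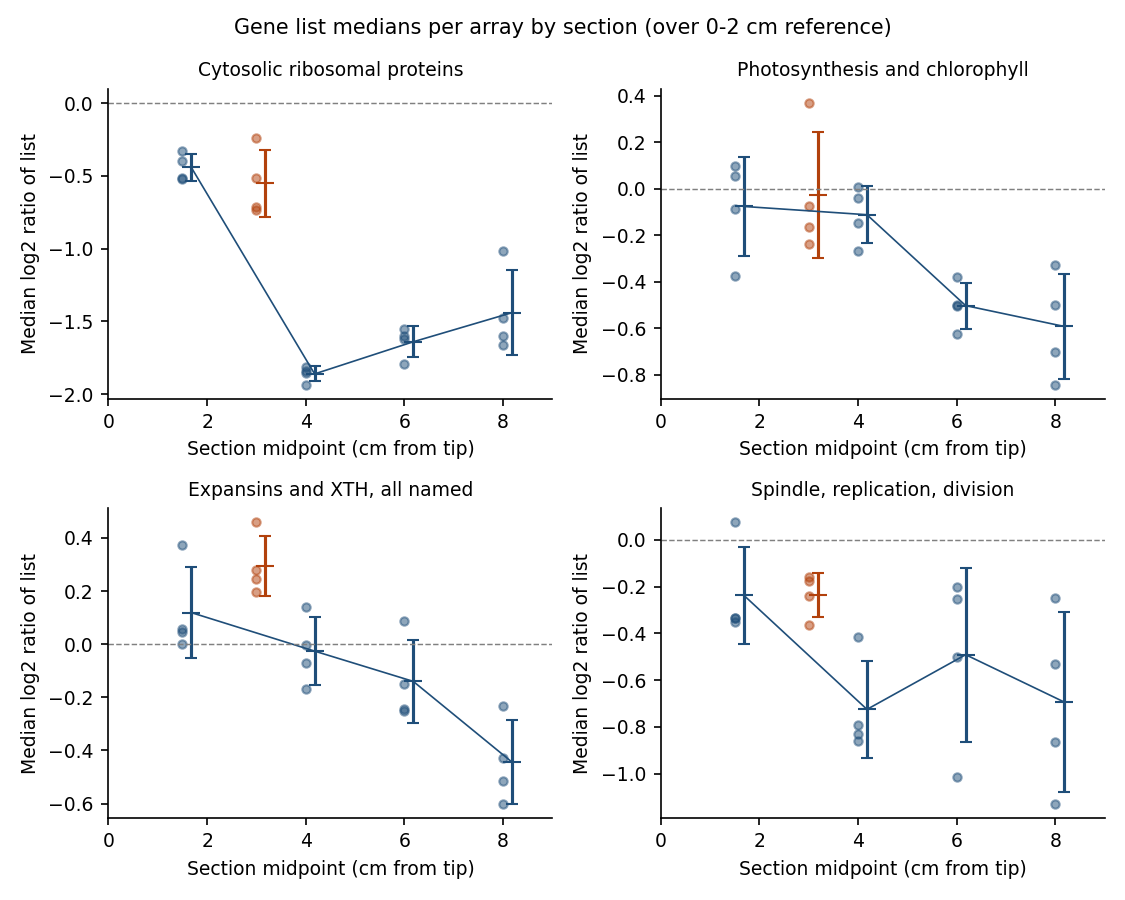
Median log2 ratio over the 0-2 cm reference of 4 added gene lists (y axis) against the midpoint of the section in cm from the tip (x axis). Points are arrays, bars the mean ± SD of 4 arrays drawn slightly to the right, blue for 10 cm stems and orange for 5 cm stems. All 12 medians of ribosomal protein genes from 3 cm downwards on 10 cm stems lay between -1.93 and -1.02.

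In the 5-7 cm section the peroxidase gene AT2G37130 was higher by 5.16 ± 0.379, GSTF3 by 4.31 ± 0.219, LTI30 by 2.26 ± 0.133 and AT3G03960 by 5.18 ± 0.154 (adjusted p = 1.32e-15). OPS (AT3G09070), a regulator of phloem differentiation, fell by 3.88 ± 0.192 (adjusted p = 3.54e-12), and AT3G16370, a GDSL lipase family gene, by 3.47 ± 0.244. EXPA8 was now lower than in the reference (-1.82 ± 0.227, adjusted p = 1.47e-06), as were EXPB1 (AT2G20750; -1.14 ± 0.153) and CSLC04 (AT3G28180), which makes the xyloglucan backbone (-1.13 ± 0.198). The auxin-responsive gene GH3.3 (AT2G23170) rose by 1.41 ± 0.202. TBL39 and TBL45 fell by 2.32 ± 0.166 and 2.13 ± 0.144, while TBL37 rose by 2.05 ± 0.149.

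Ribosomal protein genes in the 5-7 cm section had 78 of 89 down and 2 up (median -1.68, adjusted p = 2.03e-29, at most 0.00435 under the alternatives). That median was -1.64 with the scanner setting as a block, -1.68 within settings 62 and 60 and -1.67 within 63 and 60. Of 21 genes of photosynthesis and chlorophyll synthesis in an added list, 10 fell and 0 rose (median -0.36, adjusted p = 0.0178, and adjusted p = 0.121 with an estimated correlation), among them PORB (AT4G27440; -1.69 ± 0.266) and LHCB4.3 (AT2G40100; -1.296 ± 0.16). The median of that list was -0.48 with the setting as a block, -0.22 within 62 and 60 and -0.50 within 63 and 60. In the fixed photosynthesis list 2 of 8 fell, as when adjusted over the list alone, and the list was not called (median -0.038, adjusted p = 0.697). The fixed list of expansins and xyloglucan endotransglucosylases was not called either (1 up, 2 down; median 0.14, mean -0.28, adjusted p = 0.697). In all 10280 probes changed, 5078 higher and 5202 lower, against 9297 with the setting as a block, 6825 within 62 and 60 and 5069 within 63 and 60.

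The 7-9 cm section held the oldest tissue sampled. LTI30 reached 2.91 ± 0.133 (adjusted p = 8.49e-13), GSTF3 4.47 ± 0.219 and the linker histone gene HIS1-3 (AT2G18050) 2.90 ± 0.23. The peroxidase gene AT4G37520 was higher by 2.94 ± 0.248, and the 2 probes of AT2G37130 by 4.77 ± 0.426 and 4.19 ± 0.379. AT1G22410 (DHS3) rose by 2.07 ± 0.297 and the transcription factor gene LBD16 (AT2G42430) by 1.31 ± 0.171. Expression was lower for OPS (-4.18 ± 0.192), for AT1G63290, a ribulose-phosphate epimerase family gene (-4.197 ± 0.294), and for TBL45 (-2.72 ± 0.144). EXPA8 fell by 2.14 ± 0.227, XTH33 by 0.93 ± 0.172, EXPA15 by 0.89 ± 0.169, AUR2 by 2.04 ± 0.184 and PRL by 1.86 ± 0.288.

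Ribosomal protein genes had 75 of 89 down and 2 up in the 7-9 cm section (median -1.51, adjusted p = 6.36e-20, at most 0.0133 under the alternatives). The median was -1.40 with the scanner setting as a block, -1.25 within settings 62 and 60 and -1.46 within 63 and 60. Of 21 genes of photosynthesis and chlorophyll synthesis 13 fell (median -0.56, adjusted p = 0.00126), among them HEME1 (-2.20 ± 0.206), LHCB4.3 (-1.73 ± 0.16) and PRK (AT1G32060), the Calvin cycle phosphoribulokinase (-1.11 ± 0.162). The list's median was -0.62 with the setting as a block, -0.55 within 62 and 60 and -0.60 within 63 and 60. In the fixed photosynthesis list 4 of 8 fell, as when adjusted over the list alone, but the list was not called (median -0.29, adjusted p = 0.263), nor was the fixed list of expansins and xyloglucan endotransglucosylases (1 up, 3 down, the same counts adjusted over the list alone; median -0.89, adjusted p = 0.237). GUT2 (AT1G27440, IRX10), which acts in xylan synthesis, did not pass (0.08 ± 0.233, adjusted p = 0.819). It was the only member of the fixed secondary wall list with a probe named here. The fixed lists of lignification enzymes, flavonoid synthesis and jasmonate response each had a single member with a probe named here. These members passed in none of the comparisons and are not named under the rule. Altogether 11163 probes changed, 5575 higher and 5588 lower, against 10134 with the setting as a block, 7116 within 62 and 60, 6642 within 63 and 60 and 7006 without the 3 arrays whose labels name different dyes.

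The remaining comparisons set sections against each other, so that the reference dropped out of the estimate. Between the 0-3 and 3-5 cm sections of 10 cm stems, ATPMEPCRD rose by 3.03 ± 0.314 (adjusted p = 2.43e-06), TBL33 by 2.51 ± 0.362, GSTF3 by 3.53 ± 0.309, the peroxidase gene AT4G37520 by 2.79 ± 0.351 and LTI30 by 1.31 ± 0.188. HTB2 fell by 1.71 ± 0.242, TOPII by 1.86 ± 0.425, Cpn60beta2 by 2.55 ± 0.42, HEME1 by 1.28 ± 0.291 and EXLA2 by 1.51 ± 0.298. Of 89 ribosomal protein genes 68 fell, 1 rose and 20 did not pass (median -1.39, adjusted p = 1.75e-33, at most 0.00191 under the alternatives). AT3G10950 fell by 2.19 ± 0.377, and the member that rose was AT3G22230 (2.13 ± 0.204). The fixed list of expansins and xyloglucan endotransglucosylases was not called (median 0.43, adjusted p = 0.418), with EXGT-A3 higher (1.09 ± 0.242), the only member called over all probes or adjusted over the list alone. The limma test called 4378 probes, 2231 higher and 2147 lower in the 3-5 cm section, and 2508 with centring and scaling. The 3-5 cm arrays had a scanner setting of their own, which cannot be told apart from the section.

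From 3-5 to 5-7 cm, EXPA8 fell by 3.91 ± 0.321 (adjusted p = 4.49e-07), XTH33 by 1.93 ± 0.244, TBL33 by 1.89 ± 0.362, ATPMEPCRD by 1.86 ± 0.314, and the pectate lyase family gene AT1G11920 by 2.44 ± 0.21. The GDSL lipase family gene AT3G16370 was also lower (-3.175 ± 0.345). PORB, a light-dependent enzyme of chlorophyll synthesis, fell by 1.74 ± 0.376. The glucosyltransferase gene UGT72E1 rose by 1.79 ± 0.34 and the carboxypeptidase-like gene scpl18 by 1.66 ± 0.219. Of the 5 expansins and xyloglucan endotransglucosylases 3 fell, as when adjusted over the list alone (median -0.84, adjusted p = 5.19e-08), and of all 16 named members 3 fell (median -0.27, adjusted p = 0.000138, and adjusted p = 0.0626 with an estimated correlation; median -0.16 without 3-5 cm replicate 4). In all 1517 probes changed, 625 higher and 892 lower. The count was 979, 1001, 999 and 985 without 3-5 cm replicate 4, 3-5 cm replicate 3, 5-7 cm replicate 3 and 5-7 cm replicate 4. It was 769 with centring and scaling, 797 with random blocks of replicates 1 with 2 and 3 with 4, and 2915 with random blocks of 1 with 3 and 2 with 4. With the scanner setting as a block it was 835. That block leaves the setting of the 3-5 cm arrays unadjusted, which cannot be told apart from the section.

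The calls of 3 other lists between 3-5 and 5-7 cm ended when single arrays were left out. None of the 8 fixed photosynthesis genes passed in limma over all probes, and 3 fell when adjusted over the list alone (median -0.44, adjusted p = 0.0469, and adjusted p = 0.128 with an estimated correlation). That call ended without 3-5 cm replicate 1, 3 or 4 (adjusted p = 0.0629, 0.0717 and 0.0603), without 5-7 cm replicate 1 or 3 (adjusted p = 0.123 and 0.106), and with the setting as a block (median -0.54, adjusted p = 0.0589). It also ended with median centring, centring and scaling, array weights and removal of local spot trends (adjusted p = 0.0512, 0.0737, 0.0849 and 0.092). The added photosynthesis and chlorophyll list had 1 of 21 lower (median -0.33, adjusted p = 0.0303, and adjusted p = 0.128 with an estimated correlation), and its call ended without 3-5 cm replicate 1, 5-7 cm replicate 1 or 5-7 cm replicate 3 (adjusted p = 0.0532, 0.121 and 0.06), with centring and scaling (adjusted p = 0.0737) and with local spot trends removed (adjusted p = 0.0752). Ribosomal protein genes moved up, with 6 of 89 higher and 1 lower (median 0.19, adjusted p = 0.0303, and adjusted p = 0.577 with an estimated correlation), AT4G34670 by 2.75 ± 0.441. This call ended without 3-5 cm replicate 1, 5-7 cm replicate 2 or 5-7 cm replicate 3 (adjusted p = 0.0629, 0.0785 and 0.0929), and without the 3 arrays whose labels name different dyes (adjusted p = 0.0893).

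Between the 5-7 and 7-9 cm sections limma called 0 probes higher and 1 lower, at a probe without a gene name here. Of 25720 probes, 1211 had an unadjusted p under 0.05, below the share of 0.05 that chance alone would give. XTH33 and LTI30, chosen after their values were seen, did not pass. XTH33 differed by -1.07 ± 0.244 (adjusted p = 0.352) and LTI30 by 0.64 ± 0.188 (adjusted p = 0.739). In same-numbered pairs of arrays XTH33 was lower in 4 of 4 and LTI30 higher in 4 of 4. Replicate numbers were not taken to pair arrays and the genes were chosen afterwards, so these signs are no support. The XTH33 values of the sections did not overlap, so any pairing gives 4 of 4. GUT2 differed by 0.02 ± 0.33. The count was 0 without 5-7 cm replicate 2, 3 or 4 and without 7-9 cm replicate 1 or 2, 3 without 5-7 cm replicate 1 and 2 without 7-9 cm replicate 3. It was 1 with the scanner setting as a block, 0 within settings 62 and 60 and 0 within 63 and 60. Centring and scaling gave 0, random blocks of replicates 1 with 2 and 3 with 4 gave 0 and of 1 with 3 and 2 with 4 gave 9, removal of local spot trends gave 2, and 4 were called without the 3 arrays whose labels name different dyes. The 89 ribosomal protein genes shifted up as a list (median 0.19, adjusted p = 0.00263, and adjusted p = 0.253 with an estimated correlation) with no member called. That median was 0.19 with the setting as a block, 0.24 within 62 and 60 and 0.009 within 63 and 60 (adjusted p = 0.274), and the call also ended without 5-7 cm replicate 1 (median 0.14, adjusted p = 0.119) and without 7-9 cm replicate 2 (median 0.057, adjusted p = 0.351). Without the 3 arrays whose labels name different dyes it was -0.009 (adjusted p = 0.959). The fixed lists of expansins and xyloglucan endotransglucosylases (median -0.21, adjusted p = 0.0516) and of photosynthesis (median -0.31, adjusted p = 0.0534) were not called; adjusted over the list alone 1 of 5 and 0 of 8 fell.

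Across the whole 10 cm stem, the 7-9 cm section was set against the 0-3 cm section. ECS1 (AT1G31580) rose by 4.06 ± 0.216 (adjusted p = 9.26e-11), GSTF3 by 3.29 ± 0.309, HIS1-3 by 2.57 ± 0.325 and LTI30 by 2.16 ± 0.188. Among wall genes, EXPA8 fell by 3.77 ± 0.321, XTH33 by 2.57 ± 0.244, EXLA1 by 1.89 ± 0.175, EXLA2 by 2.27 ± 0.298, CSLC04 by 2.06 ± 0.28 and GH9B6 (AT1G23210), of the family 9 glycosyl hydrolases, by 1.61 ± 0.226. TBL45 (-2.86 ± 0.203) and OPS (-3.81 ± 0.271) were lower too. RCA, the Rubisco activase gene, fell by 1.44 ± 0.323, HEME1 by 1.84 ± 0.291 and PORB by 1.88 ± 0.376.

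Among all 16 named expansins and xyloglucan endotransglucosylases, 8 fell and 2 rose from 0-3 to 7-9 cm (median -0.49, adjusted p = 1.38e-05; -0.47 with the scanner setting as a block and -0.53 within settings 62 and 60). In the fixed list 3 of 5 fell and 1 rose, as when adjusted over the list alone (median -0.71, adjusted p = 0.000574, and adjusted p = 0.0647 with an estimated correlation; -0.93 as a block and -0.73 within). Of 21 genes of photosynthesis and chlorophyll synthesis 9 fell (median -0.53, adjusted p = 0.000408; -0.51 as a block and -0.57 within), while the fixed photosynthesis list had 3 of 8 lower, as when adjusted over the list alone, and was not called (median -0.42, adjusted p = 0.114). Of 89 ribosomal protein genes 43 fell and 1 rose (median -0.98, adjusted p = 7.78e-12, at most 0.0243 under the alternatives). Their median was -0.92 as a block, -0.87 within and -0.55 with centring and scaling (adjusted p = 6.62e-06 for the last). In all 5600 probes changed, 2941 higher and 2659 lower, against 5609 with the setting as a block, 3244 within 62 and 60, 2821 with centring and scaling and 3438 without the 3 arrays whose labels name different dyes.

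**Figure D3:**
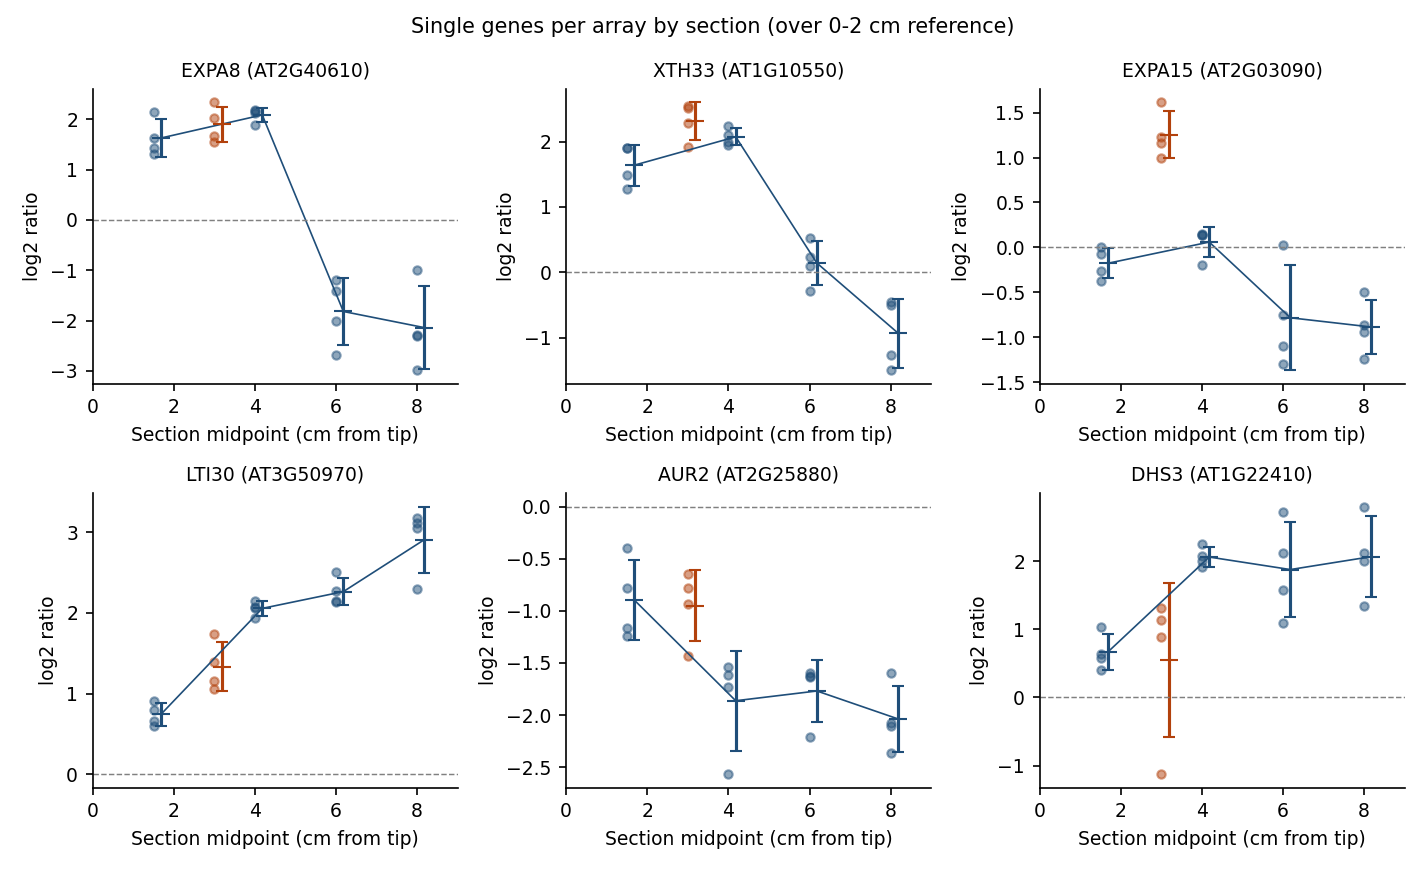
Log2 ratio over the 0-2 cm reference of 6 genes (y axis) against the midpoint of the section in cm from the tip (x axis). Points are arrays, bars the mean ± SD of 4 arrays drawn slightly to the right, blue for 10 cm stems and orange for 5 cm stems. EXPA8 was at 2.09 in the 3-5 cm section and at -1.82 in the 5-7 cm section.

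The 2-4 cm section of 5 cm stems and the 3-5 cm section of 10 cm stems lie at similar distances from the tip on stems of different length. Ribosomal protein genes were higher in the 2-4 cm section, with 61 of 89 up, 2 down and 26 not passing (median 1.23, adjusted p = 2.29e-34, at most 0.00181 under the alternatives). With centring and scaling their median was 0.80 (adjusted p = 1.05e-19). AT3G28900 was higher by 3.02 ± 0.554 and AT2G27710 by 2.42 ± 0.441. EXPA15 was higher by 1.19 ± 0.239, TBL45 by 1.12 ± 0.203 and the auxin-conjugating enzyme gene GH3.17 by 1.07 ± 0.216. The peroxidase genes AT2G37130 and AT4G37520 were lower (-4.93 ± 0.536 and -2.63 ± 0.351), as were GSTF3 (-4.03 ± 0.309, adjusted p = 4.2e-07) and the transcription factor gene TCP15 (-1.001 ± 0.2).

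Of 22 genes of spindle, replication and cell division, 6 were higher and 1 lower in the 2-4 cm section than in the 3-5 cm section (median 0.51, adjusted p = 0.043, and adjusted p = 0.199 with an estimated correlation). This call ended without 2-4 cm replicate 2 or 4 (adjusted p = 0.0778 and 0.0532) and without 3-5 cm replicate 2 or 3 (adjusted p = 0.0673 and 0.0591), and with local spot trends removed (adjusted p = 0.0767), and the median was 0.33 with centring and scaling (adjusted p = 0.039). The fixed list of expansins and xyloglucan endotransglucosylases had 1 higher and 1 lower, as when adjusted over the list alone (median -0.19, mean 0.03, adjusted p = 0.943), and the fixed photosynthesis list none (limma, 0 also adjusted over the list alone; median -0.13, adjusted p = 0.943). In all 2893 probes changed, 1402 higher and 1491 lower. The count was 1227 with centring and scaling, 4597 with array weights, 1751 with random blocks of replicates 1 with 2 and 3 with 4 and 4632 with random blocks of 1 with 3 and 2 with 4. Section, stem length, harvest day, scanner setting and array number differed together here and cannot be told apart.

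Along the 4 sections of 10 cm stems, the steepest rises among probes that met the naming rule were those of ECS1 (0.61 ± 0.032 per cm), AT1G19530 (0.60 ± 0.064) and AT1G67020 (0.54 ± 0.023). GAMMA-VPE (AT4G32940), a vacuolar processing enzyme, rose by 0.52 ± 0.049. HIS1-3 rose by 0.37 ± 0.048 and LTI30 by 0.32 ± 0.028 per cm. The steepest falls among these probes were those of AT1G63290 (-0.78 ± 0.061), EXPA8 (-0.69 ± 0.047), AT2G12910, annotated as a pseudogene (-0.68 ± 0.035), and AT3G16370 (-0.65 ± 0.051). XTH33 changed by -0.44 ± 0.036, CSLC04 by -0.35 ± 0.041, TBL45 by -0.46 ± 0.03 and RCA by -0.24 ± 0.048 per cm. A slope does not show the shape of a profile. EXPA8 was at 1.63, 2.09, -1.82 and -2.14 in the 0-3, 3-5, 5-7 and 7-9 cm sections, a step and not a steady fall.

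Of all 16 named expansins and xyloglucan endotransglucosylases 9 had a falling and 1 a rising trend (median -0.082 per cm, adjusted p = 2.33e-06). In the fixed list 3 of 5 fell, and adjusted over the list alone 3 fell and 1 rose (median -0.13, adjusted p = 3.94e-05). Ribosomal protein genes had 39 falling and 3 rising trends among 89 (median -0.14, adjusted p = 2.25e-09, at most 0.0324 under the alternatives). With centring and scaling that median was -0.072 (adjusted p = 0.000305). The fall was not steady: means of their array medians were -0.442, -1.86, -1.64 and -1.44 in the 0-3, 3-5, 5-7 and 7-9 cm sections. Photosynthesis and chlorophyll synthesis genes had 9 falling and 0 rising among 21 (median -0.099, adjusted p = 0.000173), and the fixed photosynthesis list 3 of 8 falling, 4 when adjusted over the list alone (median -0.079, adjusted p = 0.0904). A trend passed the test at 6068 probes, 3171 rising and 2897 falling, against 5670 with the scanner setting as a block and 3415 with centring and scaling. The moderated F test found differences among the 4 sections at 6581 probes, with 6016 under that block and 3519 with centring and scaling. The block leaves the setting of the 3-5 cm arrays unadjusted, so it cannot remove that setting from these counts.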

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

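The test of a wrong section label for 0-3 cm replicate 1 and the removal of local spot trends were chosen after the result was seen. Of 74 groups of 4 arrays tested, 7 held an array whose gap to the others exceeded the critical share of 0.829 of the range, and chance gives about 1 in 20. In 0-3 cm replicate 1 the median of all named expansins and xyloglucan endotransglucosylases was 0.373, against 0 to 0.058 on the other arrays. DI21 was at -2.36 in 2-4 cm replicate 4, against -1.48 to -1.39. In 3-5 cm replicate 1 the median of spindle, replication and cell division genes was -0.415 (others, -0.862 to -0.792), and AT2G37750 was at 3.35 (others, 5.78 to 6.25). AT1G03740 was at 3.26 in 7-9 cm replicate 4, against 5.71 to 6.1. In 7-9 cm replicate 2, OPS was at -3.07 (others, -4.61 to -4.5) and AT1G12570 at -5.04 (others, -3.36 to -3.02).

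Some probes changed in opposite directions from the reference in a pair of sections that also differed from each other. There were 15 such probes for 3-5 against 0-3 cm (8 higher in 3-5 cm, 7 lower) and 104 for 5-7 against 3-5 cm (31 higher in 5-7 cm, 73 lower). For 7-9 against 5-7 cm there was 1, lower in 7-9 cm. In limma 1211 of 25720 probes had an unadjusted p under 0.05 there, below the share that chance alone would give. There were 82 for 7-9 against 0-3 cm (14 higher in 7-9 cm, 68 lower) and 37 for 2-4 against 3-5 cm (24 higher in 2-4 cm, 13 lower). The fixed photosynthesis list differed by -0.445 between 5-7 and 3-5 cm, with medians of -0.038 and 0.518 against the reference; its adjusted p was 0.0469, and 0.128 with an estimated correlation, and 11 of 25 alternatives ended the call. Between 7-9 and 0-3 cm, the fixed list of expansins and xyloglucan endotransglucosylases differed by -0.709 (medians -0.887 and 0.207; adjusted p = 0.000574, and adjusted p = 0.0647 with an estimated correlation). All named members differed by -0.486 (-0.534 and 0.045) and photosynthesis and chlorophyll synthesis genes by -0.531 (-0.561 and 0.031), both at an adjusted p of 0.0243 with an estimated correlation.

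Array 0-3 cm replicate 1 correlated below 0 across probes with replicate 3 of its group (r = -0.211), which carried the opposite dye. Pairs of 0-3 cm arrays of the same dye correlated at 0.48 to 0.551 and pairs of opposite dye at -0.211 to 0.394. An effect tied to the dye was not tested for this pattern. For replicate 1, a section label from another group stays open. Its highest correlation with the mean of another group was 0.31, below those of the other 0-3 cm arrays (0.363 to 0.476). Noise particular to this array could lower its correlation with every mean whatever its label, so this test cannot decide. Among single arrays it correlated best with replicate 2 of its own group and dye (0.48), against at most 0.33 with arrays of other sections. That goes against another label, but with replicate 4 of its own group it was at 0.0138, so the values point both ways. A trend over neighbouring spots is a candidate explanation. Neighbouring spots correlated at 0.483 on replicate 1, 0.277 on replicate 3, 0.155 on replicate 4 and 0.0949 on replicate 2, and at 0.0812 or less on every array of the other sections. After removal of the running median over 51 spots, its correlation with replicate 3 was 0.134, with replicate 2 0.491 and with replicate 4 0.277. No biological explanation was tested for this pattern.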

How the results depend on the processing

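Removal of local spot trends, the scanner setting as a block, models within a scanner setting, the replicate block on the 5-7 and 7-9 cm arrays alone and the model without the 3 arrays with different dyes in their labels were chosen after the data were seen. Of the values of named genes under the alternatives, 13783 kept their direction and side of the threshold, 1003 no longer passed (471 of them with 1 array left out, 119 with centring and scaling) and 2 reversed: TUBG1 with local spot trends removed was at 0.136 in 3-5 against 0-3 cm and at 0.136 in 7-9 against 0-3 cm. Of called list shifts, judged by the direction of the test and not of the median, 727 were kept, 41 no longer passed and 1 reversed, ribosomal proteins in 7-9 against 5-7 cm (median -0.009 without the 3 arrays). The median of trichome birefringence-like genes in 2-4 cm also changed sign, from 0.005 to -0.009 with centring and scaling, -0.021 with array weights, -0.029 with local spot trends removed and -0.015 without replicate 4, while the test kept its direction. List calls numbered 31, and 19 with an estimated correlation. The causes were not tested, except that a minimum log2 leaves fewer probes by construction and models within a setting use fewer arrays. Signal over background was not analysed here. The alternative for values without a log was not run, since the values are logs.

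Counts below are of changed probes, in the order of sections given. Against the reference, for 0-3, 2-4, 3-5, 5-7 and 7-9 cm, a minimum log2 of 1 gave 186, 564, 3466, 3278 and 3718. For 3-5 against 0-3, 5-7 against 3-5, 7-9 against 0-3 and 2-4 against 3-5 cm it gave 2153, 818, 2691 and 1488, and for the trend 2732. Centring and scaling gave 2821 for 0-3 cm and 6200 for 2-4 cm against the reference. It gave 2508 for 3-5 against 0-3, 769 for 5-7 against 3-5, 0 for 7-9 against 5-7 (limma), 2821 for 7-9 against 0-3, 1227 for 2-4 against 3-5 cm, 3415 for the trend and 3519 for the F test. With only the compared arrays the 0-3 cm count was 1986. Array weights gave 2299 for 0-3 cm, 5327 for 2-4 cm and 4597 for 2-4 against 3-5 cm. Random blocks of replicates 1 with 2 and 3 with 4 gave 466 for 0-3 cm, 2169 for 2-4 cm, 797 for 5-7 against 3-5, 0 for 7-9 against 5-7 and 1751 for 2-4 against 3-5 cm. Random blocks of 1 with 3 and 2 with 4 gave 1974 for 0-3 cm, 2915 for 5-7 against 3-5, 9 for 7-9 against 5-7 and 4632 for 2-4 against 3-5 cm. The scanner setting as a block gave 835 for 5-7 against 3-5 cm. Within settings 62 and 60 the counts were 498, 6825 and 7116 for 0-3, 5-7 and 7-9 cm, 0 for 7-9 against 5-7 and 3244 for 7-9 against 0-3 cm. Within 63 and 60 they were 5069 and 6642 for 5-7 and 7-9 cm and 0 for 7-9 against 5-7 cm. Without the 3 arrays they were 7006 for 7-9 cm, 4 for 7-9 against 5-7 and 3438 for 7-9 against 0-3 cm. Removal of local spot trends gave 2 for 7-9 against 5-7 cm.

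With 1 array left out, counts ran from 336 to 941 for 0-3 cm, 1994 to 2739 for 2-4 cm, 8609 to 8927 for 3-5 cm, 8132 to 9537 for 5-7 cm and 9377 to 9913 for 7-9 cm. They ran from 3370 to 4073 for 3-5 against 0-3, 979 to 1764 for 5-7 against 3-5, 0 to 3 for 7-9 against 5-7, 4557 to 5373 for 7-9 against 0-3 and 2031 to 2288 for 2-4 against 3-5 cm. The trend gave 5045 to 6381, the F test 5310 to 6751 and list calls 28 to 35. The labels number replicates 1 to 4 in every group. After removal of group and dye, 9 of 40 same-numbered pairs of arrays correlated over 0.1 (range -0.222 to 0.247), and 7 of 20 arrays matched best with their own number, so the numbers were not taken to pair arrays. For 5-7 with 7-9 cm the same-numbered pairs 1 to 4 correlated at 0.24, 0.366, 0.454 and 0.433 after removal of group and at 0.00178, 0.158, 0.247 and 0.198 after group and dye. Arrays of different number and the same dye correlated after group at 0.0702 to 0.266, and after group and dye 5-7 cm replicate 1 matched 7-9 cm replicate 2 at 0.256. Same-numbered arrays of these sections also share dye and scanner setting. With the replicate block on these 8 arrays alone, limma called 0 probes, with XTH33 and LTI30 at an adjusted p of 0.844 and 0.844. With the replicate block the counts were 850, 3302, 10204, 10182 and 11050 against the reference, then 4260, 1465, 1, 5462 and 2851 for the pairs of sections in the order of the report, 5947 for the trend and 6332 for the F test, with 37 list calls.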

Other observations

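The test of lost signal from abundant transcripts, the models within a scanner setting and the splits for 2-4 against 0-3 cm and for 2-4 cm against a weighted mean were chosen after the result was seen. The other added lists reported here were not called in the 7-9 cm section against the reference (n = 4 arrays), and many held members that moved in both directions. Of all 25720 tested probes 43.4% changed in this section, 5575 higher and 5588 lower. Changes in both directions are therefore not particular to these lists. Of 43 class III peroxidase genes 10 rose and 9 fell (median -0.095, adjusted p = 0.76), AT1G30870 rising by 1.46 ± 0.149. Among 14 pectin methylesterase genes 2 rose and 3 fell (median -0.076, adjusted p = 0.666), with AT3G05620 at -1.57 ± 0.158. Histone genes had 1 higher and 4 lower of 11 (median -0.25, adjusted p = 0.353), HIS4 at -1.18 ± 0.125 and HIS1-3 at 2.90 ± 0.23. Spindle, replication and division genes had 3 higher and 16 lower of 22 (median -0.72, adjusted p = 0.123). Trichome birefringence-like genes had 5 higher and 2 lower of 16 (median -0.05, adjusted p = 0.76), and all named expansins and xyloglucan endotransglucosylases 3 higher and 9 lower of 16 (median -0.53, adjusted p = 0.123). Family 9 glycosyl hydrolases had 1 higher and 4 lower of 10 (median -0.23, adjusted p = 0.236), GH9C2 at -1.46 ± 0.162.

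Auxin response genes had 6 higher and 1 lower of 11 in the 7-9 cm section (median 0.38, adjusted p = 0.309), and glucosyltransferases 8 higher and 1 lower of 30 (median 0.23, adjusted p = 0.236), UGT71C2 at 1.11 ± 0.185. Of 18 serine carboxypeptidase-like genes 2 rose and 7 fell (median -0.07, adjusted p = 0.335), scpl26 at -2.07 ± 0.242 and scpl35 at -1.52 ± 0.165. Cold, drought and late embryogenesis genes had 4 higher and 1 lower of 15 (median 0.12, adjusted p = 0.236), XERICO at 1.23 ± 0.126 and DI21 at -2.63 ± 0.187. Glutathione S-transferases had 4 higher and 2 lower of 11 (median 0.31, adjusted p = 0.236). Markers of other tissue were not called: pollen, tapetum and egg cell genes had 2 higher and 3 lower of 18 (median 0.022, adjusted p = 0.909), and genes of lateral organ primordia 2 higher and 4 lower of 12 (median -0.057, adjusted p = 0.909), with TCP15 at 1.99 ± 0.141 and YAB3 at -1.01 ± 0.148.

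Ribosomal protein genes were lower in the 3-5, 5-7 and 7-9 cm sections than in the reference. Dye bias was argued against, since the list's median was below 0 on 12 of 12 arrays (-1.933 to -1.017), at -1.848, -1.671 and -1.632 with the section in Cy3 and at -1.872, -1.608 and -1.248 with it in Cy5. A loss of signal from abundant transcripts stays open: the fixed photosynthesis list had a median of 0.518 in the 3-5 cm section, where 2 of 8 members rose and 0 fell (limma), but the list was called in neither direction (adjusted p = 0.525). Harvest day, stem length and scanner setting were argued against for the difference between the 7-9 and 0-3 cm sections, which share stem length and day: among arrays scanned at 62 and 60 the list was lower in the 7-9 cm section (median -0.867, adjusted p = 3.63e-12). Against the reference, day and stem length stay open for a shift as large as that of the 0-3 cm section (median -0.475). For the further fall they were argued against, since the 3-5 cm section lay below the 0-3 cm section of the same day and stem length. There the list's median was -1.388 (adjusted p at most 0.00191 under the alternatives). The setting stays open for the 3-5 cm section. Array number stays open for all these differences, also within settings 62 and 60, since it follows the section. Lower expression away from the tip may be a biological explanation.

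The 2-4 cm section of 5 cm stems differed from the 3-5 cm section of 10 cm stems at 2893 probes, and from the 0-3 cm section at 67. Of those 67, 26 (38.8%; 7 above, 19 below) were called outside the range of both sections. The bound set for distance from the tip was 5% of the 2893, or 144 probes, which 67 cannot reach, so distance from the tip stays open. A change with distance alone, linear between section midpoints, was argued against. In limma 533 probes (203 higher, 330 lower) differed from the mean of the 0-3 and 3-5 cm sections weighted 0.4 and 0.6. Ribosomal protein genes lay 0.655 above it (cameraPR, adjusted p = 6.23e-24, and adjusted p = 0.00779 with an estimated correlation). Of the other splits of the arrays, 1 gave more, 4490. A linear change together with an effect of stem length, harvest day or scanner setting would give such differences too, so it stays open. Stem length, harvest day, scanner setting and array number stay open, since the design ties them to the section.

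Other splits of the same arrays were counted for each comparison, the real split included. For the 5 sections against the reference, 8 sign patterns are too few for a share under 0.05; in each the real pattern alone (1 of 8) reached its count. Real counts and the highest of the other patterns were 892 and 387 for 0-3 cm, 3478 and 370 for 2-4 cm, 10323 and 5 for 3-5 cm, 10280 and 698 for 5-7 cm, and 11163 and 278 for 7-9 cm. At 1 of 35 splits, the smallest share possible, the real split alone reached its count for 3-5 against 0-3 cm (4378, highest other 0 in limma). The same held for 5-7 against 3-5 cm (1517 and 0), 7-9 against 0-3 cm (5600 and 82), 2-4 against 3-5 cm (2893 and 1) and 2-4 against 0-3 cm (67 and 23). At 1 of 100 splits it held for the trend (6068 and 1215) and the F test (6581 and 842). These shares were not corrected for the number of comparisons. A grouping of these arrays by chance was thus argued against. The arrays may be technical repeats, so chance between plants was not excluded. For the 2-4 cm section against the weighted mean, 2 of 100 splits gave as many as 533 probes, which also argues against a grouping of these arrays by chance. The highest other, with 4490, put the 4 arrays of the 3-5 cm section in place of those of the 2-4 cm section, so it followed a real section, and the next gave 246. For 7-9 against 5-7 cm, 14 of 35 splits gave at least the 1 probe of the real split, so chance was not excluded. The highest, with 239 probes, set replicates 1 and 2 against replicates 3 and 4 of both sections. Scanner setting, array number and replicate number follow this split together and cannot be told apart. Within 62 and 60 and within 63 and 60 the limma count between sections was 0 and 0. Over all arrays 1211 of 25720 probes had an unadjusted p under 0.05 in limma. This is below the share of 0.05 that chance alone would give.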
